A study of Homo sapiens with 6 samples.

How the data were processed

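RNA was sequenced from Huh7 cells, an established human hepatocellular carcinoma line, carrying a short hairpin RNA against ITGB5 (3 libraries) or a control hairpin (3 libraries). Libraries came from total RNA with a directional kit, per the labels' protocols. Groups and replicate numbers were taken from the sample labels. The column codes of the deposited table were read as S for the ITGB5 hairpin and NC for the control, a reading that the labels do not spell out. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The hairpin sequences and the number of hairpins behind each group are not given in the sources used here.

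The deposited table is named for FPKM but holds whole-number counts per gene: 100% of its values were whole, and column totals differed. The values were analysed as the raw counts that the authors deposited. The aligner, the counter and its strand setting are not given in the sources used here. The table lists 58735 genes, and the identifier, position and gene type of all 58735 equalled those of GENCODE release 29 (Ensembl 94, GRCh38), while 58708 had the same symbol. The count was 0 in every library for 23888 genes. Totals were 18011313, 16563911 and 17671270 counts in the ITGB5 hairpin libraries and 17476580, 16797895 and 15777922 in the control libraries. At these totals a gene with a count of 0 could still lie at 0.167 to 0.190 CPM (counts scaled by the library total), for counting error only.

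The test planned before the data were examined was limma on log2(FPKM + 1), with edgeR as the main test if the table held counts. Since it held counts, edgeR 4.0.16 (R 4.3.3) was the main test: genes were kept by filterByExpr, libraries were scaled by TMM (factors 0.998 to 1.00), and the quasi-likelihood test compared both groups with no other covariate. P-values were two-sided and Benjamini-Hochberg adjusted over the 16577 genes kept, with a threshold of 0.05 and no fold minimum. Levels are CPM with TMM scaling. For the single comparison of ITGB5, an exact permutation test of 3 libraries against 3 was added, for which the smallest two-sided p is 0.1.

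Before the data were examined, 37 gene lists were written, holding 895 distinct genes, all matched to the table. The 35 lists with at least 5 measured genes were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the 35 lists. Camera with an estimated correlation and fry were alternatives. The named genes followed a rule also written in advance. It took ITGB5, CSNK1A1, EPS15 and EGFR, and then the 10 largest rises and 10 largest falls among protein-coding genes past the threshold whose groups did not overlap and whose mean FPKM reached 5 in a group. From each list it took up to 4 members past the threshold with the largest change, or up to 2 of the most abundant members where none passed. Some genes that the rule took are not reported here. FPKM values were computed here from the counts and the gene lengths of the table. Genes that overlap another gene were checked, because without the strand setting reads from overlapping genes cannot be told apart.

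The edgeR and camera steps were tested on simulated data for the comparison of the ITGB5 hairpin with the control, with 16577 genes. Of genes changed 1.1-fold, 30.6% were recovered, against 54% at 1.2-fold, 84% at 1.5-fold and 86% at 2-fold, and 4.95% of the calls were unchanged genes. The list given a shift was called, and so were 2 of the other lists, which held 2 of the genes that had been changed. Genes were drawn independently of each other, so the preset correlation of camera was not tested. Far fewer genes were changed than passed in the real data, so recovery there may differ.

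For words in 3′ untranslated regions (UTRs), 1 principal transcript per protein-coding gene was taken from GENCODE 29, which gave a 3′ UTR for 13317 of 13403 tested genes (99.4%). Each of 16119 words of 7 bases, in 10118 genes with a mean log2 CPM of at least 3, was compared between genes with and without it, after adjusting for 3′ UTR length and GC content. Its significance was set against the largest absolute z over all words in each of 1000 permutations of the genes. In simulated values for these 10118 genes, a word given a shift ranked 1.

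Alternatives were limma on log2(FPKM + 1) with pseudocounts 0.1, 1 and 5, other scalings, other filters, DESeq2 1.42.0, a fold minimum, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were edgeR with RLE factors, with library totals only, with the replicate block, with a minimum fold of 1.2, and without genes that hold a word described below in their 3′ UTR. No mapped column of the table was left out.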

Results

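The series asked what changes in the transcriptome of Huh7 hepatoma cells when ITGB5, the integrin beta 5 subunit, is knocked down. RNA-seq gene counts were compared between 3 libraries with the ITGB5 hairpin and 3 with a control hairpin. Each library held 15777922 to 18011313 counts. Mitochondrial transcripts took 3.24% to 3.29% of the counts in the ITGB5 hairpin libraries and 3.47% to 3.54% in the controls, and lincRNA, antisense and sense intronic genes took 0.792% to 0.806% against 0.840% to 0.848%. Between 25856 and 26143 genes were above 0 in the ITGB5 hairpin libraries and between 26795 and 26976 in the controls.

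ITGB5 mRNA was lower in all 3 knockdown libraries than in all 3 controls, but it remained abundant. ITGB5 (ENSG00000082781, chromosome 3, 124761948 to 124901418, minus strand, GRCh38) lay at 211.8 CPM ± 6.35 (SD, n = 3) in the controls and at 176.1 CPM ± 4.30 (SD, n = 3) with the hairpin. That was 16.8% lower (95% interval 13.04% to 20.46%), a log2 change of -0.27 with an SE of 0.032 (edgeR, Benjamini-Hochberg adjusted p = 2.13e-09). The exact permutation test gave p = 0.1, the smallest p that 3 libraries against 3 allow.

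Of the other genes in the series title, EGFR, the epidermal growth factor receptor, was slightly lower, whereas no change passed the test for the kinase CSNK1A1 or the endocytic adaptor EPS15. EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628) fell from 788.4 CPM ± 17.0 to 740.6 CPM ± 9.89 (SD, n = 3 each), which was 6.07% lower (edgeR, Benjamini-Hochberg adjusted p = 0.00272, and 0.000586 adjusted over the list alone of these 3 genes). EGFR did not pass in any limma fit except that with quantile normalization, with a limma adjusted p of 0.0597 at a pseudocount of 1. The EGFR 3′ UTR holds 1 copy of a 7-base word, AGACCAA, that was common among genes that fell. CSNK1A1 (ENSG00000113712, chromosome 5) lay at 146.6 CPM ± 5.02 in the controls and 140.1 CPM ± 3.96 with the hairpin (edgeR adjusted p = 0.254, and 0.111 adjusted over the list alone). EPS15 (ENSG00000085832, chromosome 1) lay at 42.8 CPM ± 1.32 and 42.4 CPM ± 0.773 (edgeR adjusted p = 0.944, and 0.855 adjusted over the list alone).

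**Figure D1:**
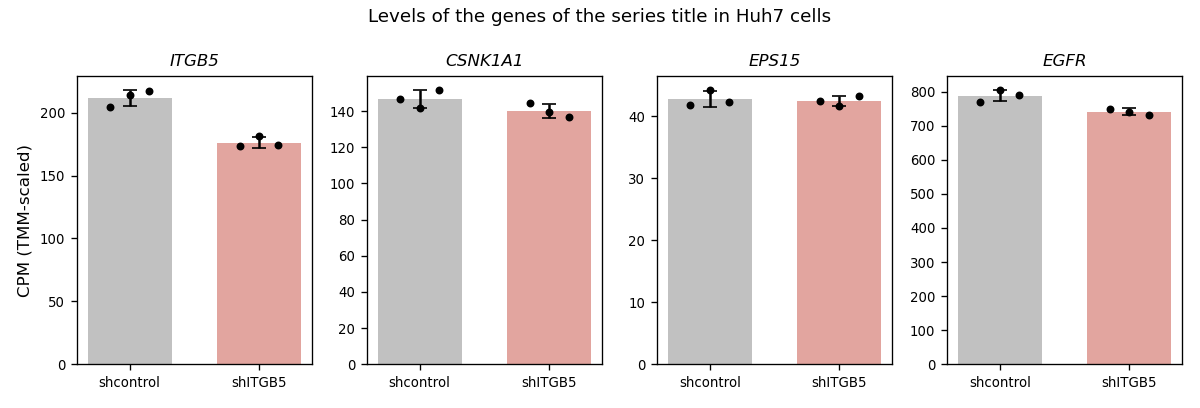
CPM (vertical axis, TMM-scaled counts, starting at 0) of ITGB5, CSNK1A1, EPS15 and EGFR in control and ITGB5 hairpin libraries; bars are means, error bars the SD and points the 3 libraries of each group. ITGB5 averaged 176.1 CPM with the hairpin against 211.8 CPM in the controls, and the groups of CSNK1A1 and EPS15 overlapped.

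Many genes differed between the groups, mostly by small amounts. Of 16577 genes tested, 2495 (15.05%) passed the threshold, of which 1377 rose and 1118 fell (edgeR, Benjamini-Hochberg adjusted p under 0.05). The median absolute change among them was 1.16-fold, and 17 genes rose and 40 fell at least 2-fold. The groups did not overlap for 28.5% of the genes tested, against 10% by chance for 3 libraries against 3. Among the 13299 genes kept for limma, limma with the replicate block called 735 and limma without trend or robust fitting 917.

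The largest rises included the EGFR ligand EREG, the secreted netrin NTN4 and the chemokine CXCL1. EREG rose from 18.6 CPM ± 1.78 to 38.2 CPM ± 2.13 (log2 change 1.04, SE 0.077), and OGFR from 51.3 CPM ± 1.77 to 97.9 CPM ± 3.21 (0.93). NTN4 (0.82), CXCL1 (0.79), GXYLT1 (0.77), CDK14 (0.77), TUFT1 (0.74), MESD (0.73) and RGS19 (0.73) were also among the 10 largest, each with an edgeR adjusted p of at most 1.57e-05. CDK14 overlaps CLDN12, whose counts equalled 88.5% of those of CDK14. The 3′ UTRs of GXYLT1, CDK14, TUFT1 and MESD hold TCGGAGA or its shifted form CGGAGAA, and that of GXYLT1 also holds GACCAAA.

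The largest falls included ARPC5, a subunit of the actin-nucleating Arp2/3 complex, and LIN28B, an RNA-binding protein that blocks let-7 maturation. ARPC5 (chromosome 1, 183620846 to 183635757) fell from 239.4 CPM ± 2.65 to 111.8 CPM ± 2.09 (log2 change -1.10, SE 0.033), and LIN28B from 282.4 CPM ± 1.48 to 161.0 CPM ± 2.45 (-0.81, SE 0.030). EVA1B (12.98 to 6.46 CPM), B3GNT2 (log2 change -0.94), LRRFIP1 (-0.89), SLC18B1 (-0.70), PLAU (-0.64), BIRC3 (-0.60) and PNP (-0.60) were also among the 10 largest, each with an edgeR adjusted p of at most 6.84e-09. EVA1B overlaps SH3D21 on the other strand, whose counts equalled 106% of those of EVA1B. The 3′ UTRs of 8 of the 10 hold AGACCAA or its shifted form GACCAAA. The noncoding RNA MALAT1, named after its values were seen, also fell, from 369.4 CPM ± 11.3 to 174.1 CPM ± 7.97 (log2 change -1.08), and holds neither form.

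Of the 35 lists tested, 11 passed the threshold, 9 upward and 2 downward (camera, Benjamini-Hochberg adjusted), and 7 of them also passed with an estimated correlation. Cell cycle lists moved apart: genes of G2 and M phase were lower and genes of S phase were higher. Of 25 G2/M genes, 19 fell, 1 rose and 5 did not pass, or 23 and 1 adjusted over the list alone. HMMR (-0.42), KIF20A (-0.41), CDC20 (-0.36) and CCNB1 (-0.35), which encode mitotic regulators, fell most on the log2 scale. BIRC5 was the gene that rose (0.29), named after its values were seen. Of 25 S phase genes, 17 rose and 8 did not pass, or 19 rose adjusted over the list alone, led by GINS2 (0.39), MCM5 (0.35), CDT1 (0.30) and MCM2 (0.29). Both lists held with an estimated correlation (adjusted p = 0.0118 for each). GINS2, KIF20A and MCM2 overlap other expressed genes.

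**Figure D2:**
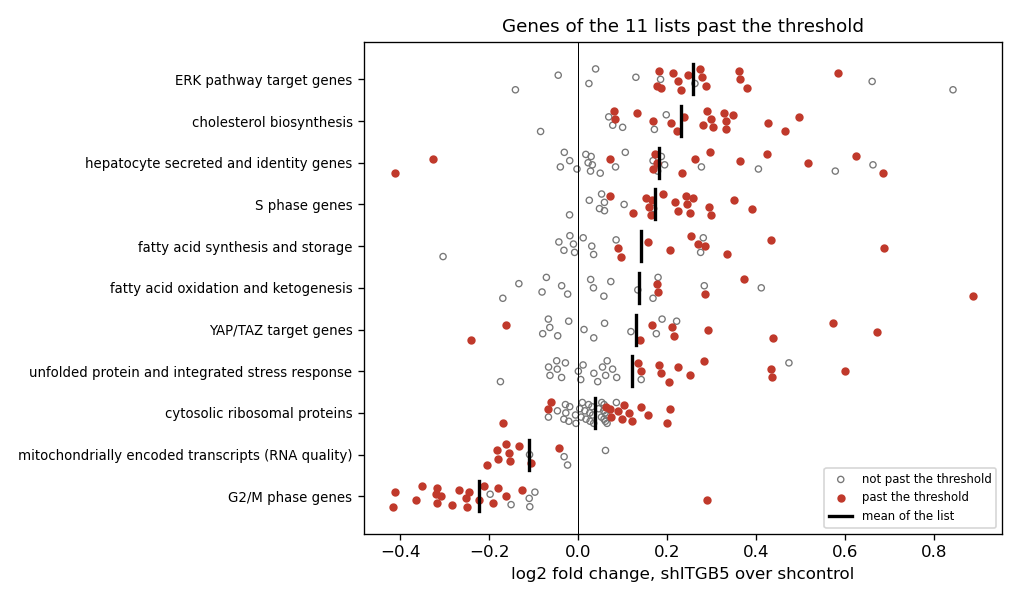
Log2 fold change of shITGB5 over shcontrol (horizontal axis) for each measured gene of the 11 lists past the threshold; filled points passed the threshold, open points did not, and black bars are list means. The G2/M list had a mean of -0.22 and the cholesterol biosynthesis list a mean of 0.23.

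Lipid synthesis genes rose. Of 24 cholesterol biosynthesis genes, 18 rose and 6 did not pass, or 20 rose adjusted over the list alone. MVD (0.50), INSIG1 (0.46) and MVK (0.43) led, and MVK overlaps MMAB and holds CGGAGAA in its 3′ UTR. Of 22 fatty acid synthesis and storage genes, 10 rose and 12 did not pass, or 11 rose and 1 fell adjusted over the list alone, with GPAM (0.69), PNPLA3 (0.43), FADS2 (0.33) and SREBF1 (0.28) the largest. PNPLA3 overlaps SAMM50 on the same strand, whose counts equalled 370% of those of PNPLA3, and FADS2 and SREBF1 also overlap other expressed genes. Camera gave adjusted p = 0.0118 and 0.0215 for these lists with an estimated correlation. Of 20 fatty acid oxidation and ketogenesis genes, 5 rose and 15 did not pass, or 6 rose adjusted over the list alone. FABP1 (0.37) and ECI1 (0.28) were among those that rose, and the list's call was lost (adjusted p = 0.138 with an estimated correlation).

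Targets of ERK signalling, stress-response genes and hepatocyte genes also rose. Of 23 ERK target genes, 14 rose and 9 did not pass, or 18 rose adjusted over the list alone, among them the transcription factors EGR1 (0.58), ETV5 (0.38) and JUN (0.36), and IER3 (0.36). EGR1 missed the threshold without shcontrol replicate 1 or shITGB5 replicate 1 (edgeR adjusted p = 0.0577 and 0.0806). Of 30 genes of the unfolded protein and integrated stress response, 11 rose and 19 did not pass, or 13 rose adjusted over the list alone, led by TRIB3 (0.60), ATF3 (0.43), DDIT3 (0.43) and PPP1R15A (0.28). DDIT3 overlaps MARS and MBD6, which carry far more counts. Of 34 hepatocyte secreted and identity genes, 12 rose, 2 fell and 20 did not pass, or 14 and 2 adjusted over the list alone. The plasma protein genes TTR (0.68), APOA2 (0.52) and AHSG (0.42) and the receptor ASGR1 (0.62) rose, whereas the transcription factors ONECUT1 (-0.41) and NR5A2 (-0.33), named after their values were seen, fell. AHSG missed the threshold without shcontrol replicate 3, shITGB5 replicate 1 or shITGB5 replicate 3 (edgeR adjusted p = 0.271, 0.0519 and 0.148). The ERK, stress-response and hepatocyte lists passed with an estimated correlation (camera adjusted p = 0.0174, 0.0327 and 0.0215). Of 22 YAP/TAZ targets, 8 rose, 2 fell and 12 did not pass, or 9 and 3 adjusted over the list alone. ANKRD1 (0.67), CYR61 (0.57) and CTGF (0.44) rose most, and this call was lost (adjusted p = 0.0538 with an estimated correlation).

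Mitochondrially encoded transcripts, written as a list of RNA quality, were lower: of 13, 9 fell and 4 did not pass, also adjusted over the list alone. MT-ND5 (-0.21), MT-ND6 (-0.18), MT-ATP6 (-0.18) and MT-CYB (-0.16) fell most, and the call was lost (adjusted p = 0.0861 with an estimated correlation). Nuclear-encoded respiratory chain genes did not pass as a list (7 of 31 rose and 2 fell, camera adjusted p = 0.501). Of 46 cytosolic ribosomal protein genes, 12 rose, 3 fell and 31 did not pass, or 17 and 4 adjusted over the list alone. RPL37A (0.21) and RPL38 (0.20) rose, RPL19 (-0.17) fell, and the call was lost (adjusted p = 0.563 with an estimated correlation, and 0.119 by camera without shITGB5 replicate 3). Ribosomal protein genes have many near-identical pseudogene copies, so their values are uncertain.

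Lists tied to integrins and EGFR trafficking did not pass as lists, although some members did. Of 15 integrin subunits, 2 rose (ITGA1 0.15, ITGAV 0.08) and ITGA7 fell (-0.47), with a camera adjusted p of 0.935. ITGAV missed the threshold without shcontrol replicate 1, shcontrol replicate 3 or shITGB5 replicate 3 (edgeR adjusted p = 0.157, 0.126 and 0.176), and ITGA7 without any library except shITGB5 replicate 2 (0.0519 to 0.108). ITGA1 and ITGA7 overlap other expressed genes, as do AHSG, CSNK1A1, ERBB2, GPX2, MT-ATP6 and TXNRD1. Of 34 focal adhesion genes, 2 rose and 5 fell (adjusted p = 0.316), including ACTN4 (-0.17) and TNS1 (0.27). Of 39 endocytic adaptor and sorting genes, 2 rose and 5 fell (adjusted p = 0.304), including CLTB (0.23) and VPS4B (-0.24), the latter lost without shcontrol replicate 2 (edgeR adjusted p = 0.0719). Of 20 EGFR family, ligand and adaptor genes, 5 rose and 2 fell (adjusted p = 0.172). The ligands EREG (1.04), BTC (0.68) and AREG (0.61) and the receptor ERBB2 (0.26) rose, with BTC lost without shcontrol replicate 2 (edgeR adjusted p = 0.0576). None of the 6 casein kinase 1 genes passed (camera adjusted p = 0.818). Of 9 measured kinases targeted by multi-target inhibitors, FGFR3 (0.46) and FGFR4 (0.25) rose and BRAF (-0.31) fell (adjusted p = 0.088). BRAF holds GACCAAA in its 3′ UTR and overlaps NDUFB2. Of other list members named here, CDC20, VPS4B, SAMD9 and GPX2, which fell, also hold AGACCAA or GACCAAA. So do GINS2, FADS2, CTGF, ITGA1 and TNS1, which rose.

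The other lists did not pass either. Camera adjusted p was 0.0714 for interferon-stimulated genes, of which 0 of 25 rose and 6 fell, with SAMD9 (-0.67) and HERC5 (-0.63) the largest falls. It was 0.0991 for NRF2 targets (3 of 26 rose and 10 fell, with GPX2 at -0.57 and TXNRD1 at -0.26), where the mean and the test were negative and the median positive. It was 0.156 for NF-kB and inflammatory genes (6 of 22 rose and 2 fell, with CXCL8 at 0.50), where the test was upward and the mean and median negative. It was 0.0855 for drug transporters (2 of 14 rose, ABCB1 0.14 and ABCC6 0.14, the latter lost without shcontrol replicate 1, shcontrol replicate 2 or shITGB5 replicate 2, edgeR adjusted p = 0.0615, 0.234 and 0.107) and 0.098 for each of gluconeogenesis (2 of 11 rose), complement and coagulation (7 of 29 rose and 1 fell) and glycolysis and hypoxia (2 of 26 rose and 6 fell). It was 0.134 for bile acid synthesis (2 of 12 rose and 1 fell), 0.163 for hepatoma and fetal liver genes (3 of 20 rose, with AFP at 0.30, and 5 fell) and 0.262 for EMT and matrix genes (7 of 29 rose, with THBS1 at 0.54, and 5 fell, with TNC at -0.66). It was 0.508 for apoptosis regulators (7 of 28 rose and 4 fell), 0.604 for each of epithelial junction genes (4 of 20 rose and 4 fell) and p53 targets (3 of 19 rose and 3 fell), and 0.697 for drug-metabolizing enzymes (3 of 23 rose, with CYP1A1 at 0.71, and 2 fell). It was 0.797 for WNT targets (2 of 15 rose and 3 fell), where the mean was negative and the test upward, and 0.935 for TGF-beta pathway genes (4 of 21 rose and 4 fell), where the mean was positive and the test downward. Among markers of other cell types, 1 of 9 fibroblast and stellate genes rose (LUM 0.22, camera adjusted p = 0.264). Endothelial markers (2 measured) and blood and immune markers (3 measured) were too few to test.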

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

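The edgeR fits with RLE factors, library totals, the replicate block or a fold of 1.2, and the fit without word genes, were chosen after the data were seen. The 2495 genes (1377 up, 1118 down) became 1445 (795, 650) with limma on log2(FPKM + 1), 1438 (790, 648) at pseudocount 0.1 and 1447 (793, 654) at pseudocount 5. They became 1430 (785, 645) with median scaling, 1463 (736, 727) with quantile normalization, 1423 (802, 621) on TPM and 917 (517, 400) without trend or robust fitting. A log2 change of at least 1 left 57 (17, 40), and edgeR against a fold of 1.2 left 149 (83, 66), by construction. Leaving out word genes left 717 falls of 1807 calls, again by construction. For the limma fits the cause was not tested. DESeq2 called 1914 genes, and leaving out 1 library gave 1939 to 2183. No gene called in both the main test and an alternative changed direction. Same-numbered libraries did not vary together (correlations 0.028, -0.000125 and -0.0174), which does not exclude that they shared a day or culture. The replicate block in limma called 735 genes (430, 305), and in edgeR 2303. ITGB5 kept its direction throughout, and its log2 change of -0.2659 failed only the minimum of 1 and the test against a fold of 1.2. EGFR failed both at -0.0903. It also missed the threshold in limma at -0.0917 (base fit, no trend, block), -0.0931 and -0.0862 (pseudocounts 0.1 and 5), -0.0921 (median scaling) and -0.0915 (TPM). Some values that passed no test changed sign. EPS15 ranged from -0.0303 to 0.0129 when 1 library was left out. CSNK1G2, at 0.0004, became -0.0017 (limma base, pseudocount 0.1, no trend, block), -0.0016 (pseudocount 5), -0.002 (median scaling), -0.0166 (quantile), -0.0003 (TPM), -0.0057 (mean FPKM at least 5), -0.0008 (DESeq2, RLE) and -0.003 (library totals). With 1 library left out, CSNK1G2 ranged from -0.0442 to 0.0354 and PECAM1 from -0.1261 to 0.1956. The 11 lists (9 up, 2 down) became 20 (17 up) with no low-count filter, 7 (1 down) with an estimated correlation and 26 (19 up, 7 down) with fry, which does not compare a list with other genes. They became 10 (8 up) in each limma fit except that with quantile normalization, and 9 (7 up) with quantile normalization and at a mean FPKM of at least 5. Fatty acid oxidation was lost in all of these (camera adjusted p of 0.104 to 0.175), and ribosomal proteins with quantile normalization (0.834), at a mean FPKM of at least 5 (0.0812) and with fry (fry adjusted p = 0.216). Drug transporters passed without shITGB5 replicate 3 (camera adjusted p = 0.0405) and complement without shITGB5 replicate 2 (0.0489). At this depth and with 3 libraries per group, simulated changes of 1.1-fold were recovered for 30.6% of genes, with far fewer genes changed than passed here.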

Other observations

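The tests of site number for the lower words, of the miR-133 word and of EGFR among genes with its kind of site were set before their results were seen. The test of the number of lists in other splits was set before the list counts were seen, but after the gene counts of the same splits. The tests of site number for the higher words, of 3′ UTR length and GC content, of the lists without word genes, of the number of knockdown groups, of the genes in other splits, and of single lists and an estimated correlation in other splits were chosen after. The 7-base words and the control sequence below were also picked after the data were seen.

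Genes grouped by 7-base words in their 3′ UTR moved with the hairpins. Genes with GACCAAA or AGACCAA were lower with the ITGB5 hairpin (z = -14.7 and -12.1), the lowest 2 of 16119 words. Genes with TCGGAGA or CGGAGAA were higher (z = 9.58 and 8.81), the highest 2. Each had a permutation p of 0.001, the smallest that 1000 permutations can give, and the largest absolute z in the permutations was 6.06. These permutations, and the SEs given for words, take genes as the units and do not measure the spread between libraries. Of genes that fell, 360 of 1038 (34.7%) held a lower word, against 14.6% of those not past the threshold, and of genes that rose, 120 of 1332 (9.01%) held a higher word, against 2.73%. These shares restate the choice of the words and are no further evidence. By region, without adjusting for length or GC content, genes with a lower word in the 3′ UTR alone differed from genes without it by -0.0736 ± 0.0054 (SE). The difference was -0.0441 ± 0.0036 for the coding region alone and -0.017 ± 0.0174 for the 5′ UTR alone.

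For these words, 3′ UTR length or GC content as the whole cause is argued against by the smallest absolute z of 8.81 after adjusting for both. Genes with GGACCAA, the match to the miR-133 seed, and neither lower word differed by -0.0097 ± 0.0075 (SE) from genes with no site. Genes with a 7-base match to AGACCAA differed by -0.0373 ± 0.0072 (SE). The latter can also hold GACCAAA, which the former lack. The gap between them therefore does not decide on a cellular microRNA with the miR-133 seed, which stays open. Also open is that each hairpin may repress transcripts matching its seed, guide positions 2 to 8. As such repression would give, 308 genes with 2 or more lower-word sites were lower than 1345 genes with 1 site by -0.0402 ± 0.0125 (SE). A cellular microRNA matching these words could give the same, so this does not single out the hairpin. Longer and shorter matches were counted alike, so site number is not separated from match length. For the higher words no test decides: the 21 genes with 2 or more sites differed from the 347 with 1 site by -0.0003 ± 0.0544 (SE), and are too few. TCGGAGA pairs with positions 2 to 8 of a commonly used non-targeting sequence, TTCTCCGAACGTGTCACGT, known from background and not from the sources used here. The same positions of its complement pair with TGTCACG, whose z of 1.68 lay inside the permutation range, and the sources do not give which strand would act as the guide. The ITGB5 transcript ENST00000296181.8 holds AGACCAA once, in coding exon 4 of 15 (chromosome 3, 124848321 to 124848327, GRCh38), but 21.7% of all 7-base words occur in that transcript.

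The list changes may come from loss of ITGB5, from the hairpins acting elsewhere, from both, or from another difference between the groups. The labels do not say whether the 3 libraries of a group came from separate cultures, so a culture difference cannot be told apart. Members that carry a word do not account for the list changes directly. Without genes holding either word, 10 of the 11 lists stayed past the threshold in their direction. Fatty acid oxidation did not (camera adjusted p = 0.0746), though its mean log2 change was 0.131 without these genes and 0.137 with them. Effects downstream of repressed word genes are not excluded by leaving those genes out. Loss of ITGB5 itself cannot be told apart from other effects of the hairpin, because the labels tell apart 1 knockdown group and ITGB5 fell by 16.8%. In 1 of 10 splits of the libraries, the real one, as many as 11 lists passed, and the highest other had 8 (0 against 7 with an estimated correlation), but every other split keeps 2 libraries of a group together and so part of the group difference, and 10 splits are too few for a share under 0.05. With the preset correlation, the G2/M and cholesterol biosynthesis lists passed in all 9 other splits, the S phase list in 8 and the ERK target list in 6, and only 3 of the 11 lists passed in no other split.

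The EGFR 3′ UTR holds a 7-base match to AGACCAA, which may contribute to its fall of 6.07%. Of 652 other genes with the same kind of site, 29.6% changed by as much downward or more, as did 18.2% of 7539 genes with no site. The seed match and an effect of ITGB5 loss cannot be told apart for EGFR, since its change lies inside the middle 90% of both groups of genes.

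The count of 2495 genes was reached in 1 of the 10 splits of the 6 libraries, the real one, and the highest other split gave 1 gene. Every other split mixes both groups, so the group difference adds to its spread and by itself keeps its count low. With 10 splits, no share under 0.05 is possible.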
